A study of Mus musculus with 8 samples.

How the data were processed

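RNA was sequenced from derivatives of a cell line grown from a liver metastasis of a mouse with pancreatic cancer. The mice of origin (KPCT) carry conditional mutant alleles of Kras and p53, a Pdx1-driven Cre recombinase and a Tomato reporter. A control derivative carrying a short hairpin RNA against GFP and a derivative labelled Blimp1 knockdown were each cultured at 20% or 0.5% O2 for 24 hours. Each of the 4 combinations has 2 libraries (Illumina TruSeq), 8 in all. Blimp1 is the protein of the gene Prdm1, a transcriptional repressor best known from lymphocytes.

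Per the submitters' processing notes, reads were aligned with STAR 2.4.2a and counted with HTSeq, with mm10 as the genome build. The gene annotation and the strand setting of the counting were not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. The deposited table holds raw read counts per gene symbol, which the authors had not normalized. The table has 30743 genes and 5 entries that name no gene (reads without a feature, ambiguous reads, reads aligned to several places and the like). These entries held between 27.35% and 29.95% of all reads of a library and stayed out of library sizes and tests. Reads without a feature were 4.695% to 5.497% in normoxic and 7.029% to 8.168% in hypoxic libraries. A further 25 symbols had been turned into dates by spreadsheet software and were left as they are. Positions are those of GENCODE M21 on GRCm38, the assembly of mm10, matched by symbol.

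The gene counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10), which left 13004 genes, and library sizes were scaled with TMM factors. Negative binomial models with 1 mean per group were fitted to all 8 libraries with 4 residual degrees of freedom, and the robust quasi-likelihood F test was applied to 5 contrasts. The contrasts were low against normal oxygen in control cells and in knockdown-labelled cells, knockdown-labelled against control cells at each oxygen level, and the interaction. The interaction is the response to low oxygen in knockdown-labelled cells minus that in control cells. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and genes with an adjusted p below 0.05 were called. The common biological coefficient of variation was 2.06%, so that small changes were called. For that reason a second count of called genes with a change of at least 2-fold, chosen after the data were seen, is given beside the first. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Standard errors are the absolute log2 fold change over the square root of F. Where a group has few counts, these standard errors can be smaller than counting error alone. CPM values, in the usual sense of reads scaled by library size, use the TMM-scaled library sizes.

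Where a gene had no count in a group, its fold change is a lower bound against a floor of 3 counts over that group. Where a group had 1 to 3 counts, the ratio of CPM is given with a 95% exact interval for counts, or the counts alone are given. Interaction terms are fitted values throughout. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Library totals ranged from 10536931 to 14117987 gene counts, so that 3 counts in 1 library equal 0.209 to 0.299 CPM.

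Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the lists within a contrast. The 26 lists cover glycolysis, HIF targets outside glycolysis, the mitochondrial respiratory chain (nuclear genes), mitochondrially encoded genes, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and p53 targets, the ATF4 and amino acid response, endoplasmic reticulum chaperones, the interferon response and antigen presentation, NF-kB and inflammatory cytokines, Blimp1 targets known from lymphocytes, epithelial genes, mesenchymal genes, extracellular matrix and collagen processing, pancreatic and ductal lineage factors, cholesterol biosynthesis, Kras and MAPK output, cytosolic ribosomal proteins, ribosome biogenesis, structural and nuclear RNAs, and markers of immune cells, fibroblasts, endothelial cells, hepatocytes, and acinar and endocrine pancreas. Of 645 listed symbols, 625 were found under their own symbol, 4 under an older one and 16 not at all. The 22 lists with at least 3 tested members entered the test. List members past the edgeR threshold were counted over all genes tested and, where that differs, also adjusted over the list alone.

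The tests, the gene lists, the alternatives except those said to be added, and the rule for named genes were chosen before the data were examined. By that rule the text names Prdm1 and, for each comparison of 2 groups, the 8 genes with the largest rise and the 8 with the largest fall in fitted log2 fold change. These had to be called, have a mean log2 CPM of 3 or more, and have both libraries of one group above both of the other. Genes with Gm, LOC, Rik or clone names and pseudogenes were passed over. For the interaction the 6 largest terms each way are named, without the condition on the order of libraries. For a list that passed its test or had at least 3 called members, up to 4 called members with the smallest p may be named. A list without a called member may be represented by its most abundant member.

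The alternatives were RLE and upper-quartile factors, no filter beyond 1 count in any library, DESeq2 1.42.0, limma voom, the replicate number as a block, a fit of only the 4 libraries of a comparison, and leaving out each library in turn. For the lists they were an estimated inter-gene correlation and the fry test. A likelihood ratio test of edgeR with an assumed biological coefficient of variation of 0.1 was added after the data were seen. Correlations of log2 fold changes were computed across genes, which are not independent replicates, and carry no p-value. Low oxygen in control cells and the comparison of the lines in hypoxia share the control hypoxia libraries, so 20 simulations of unchanged groups gave the covariance expected from sharing alone.

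The tests were checked on simulated counts for the comparison of oxygen levels in control cells. Means came from the control normoxia libraries, depths from all 8 libraries, and the spread was the one fitted to these data. The rate of false calls therefore holds only if that spread is right. At each fold 50 genes were changed, far fewer than were called in these data, so scaling under a broad response was not checked. Over 11798 genes, edgeR called 46% of genes changed 1.2-fold, 86% of those changed 1.5-fold, 84% of those changed 2-fold, 100% of those changed 4-fold, and 0.0604% of unchanged genes. In a second simulation over 11783 genes, camera called the raised list and 0 of 40 unchanged lists. The simulated genes were drawn independently, so this check cannot show false calls that correlated genes would bring.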

Results

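Gene expression was measured by RNA sequencing in a mouse cell line from a liver metastasis of pancreatic cancer after 24 hours at 20% or 0.5% O2, in a control derivative and a derivative labelled Blimp1 knockdown. The 4 groups had 2 libraries each. Gene counts per library were 13972838 and 10536931 for control cells in normoxia, 10540328 and 14117987 for control cells in hypoxia, 12622591 and 12155415 for knockdown-labelled cells in normoxia, and 10805549 and 12273626 for knockdown-labelled cells in hypoxia. The first principal component of log2 CPM held 66.96% of the variance and separated the oxygen levels, and the second held 21.93% and separated the lines. Replicate libraries lay close together, with a median absolute log2 difference per gene of 0.074 to 0.093 over the 13004 tested genes. Their spread was unequal. For genes with at least 100 counts, the mean squared deviation over that of counting error was 2.088 (control) and 2.301 (knockdown-labelled) in normoxia. In hypoxia it was 1.098 and 1.188. The spread pooled over all groups may thus be too small for the normoxic comparison of the lines.

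Prdm1, the gene of Blimp1 (chromosome 10, 44437177 to 44528501, minus strand, GRCm38), is the target that the knockdown label names and was read first in every library. Control cells had 0 and 0 counts in normoxia and 64 and 69 counts in hypoxia. Knockdown-labelled cells had 4 and 2 counts in normoxia and 30 and 49 counts in hypoxia. Mean levels were 0 CPM, 5.38 ± 0.804 CPM, 0.25 ± 0.111 CPM and 3.17 ± 0.811 CPM in these groups in this order (SD, n = 2). Hypoxia thus came with Prdm1 mRNA at least 41.2-fold higher in control cells (edgeR adjusted p = 1.57e-25), against a floor of 3 counts over the group. In knockdown-labelled cells the ratio was 12.8 (95% counting interval 5.61 to 35.8, edgeR adjusted p = 2.02e-13). In hypoxia the knockdown-labelled cells had less Prdm1 than control cells, with a log2 fold change of -0.72 (SE 0.21, edgeR adjusted p = 0.00141). That call was lost with DESeq2 (adjusted p = 0.0997) and in edgeR without the first knockdown-labelled hypoxia library (-0.50, adjusted p = 0.0704). In normoxia the difference went against the label, with 6 counts in the knockdown-labelled libraries and 0 in the control libraries (edgeR adjusted p = 0.0155). It was no longer called in 3 of the 4 fits that left out a normoxic library, with edgeR adjusted p of 0.065, 0.0884 and 0.111. The fitted interaction for Prdm1 was -5.39 (SE 1.7, edgeR adjusted p = 0.00392), a value that depends on the prior count because of the empty group. The normoxic counts lie near or below the floor of 3 counts per library and are too few to judge the knockdown. The hypoxic libraries go with the label, but that call was not kept in every fit. These cells are therefore called knockdown-labelled throughout.

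**Figure D1:**
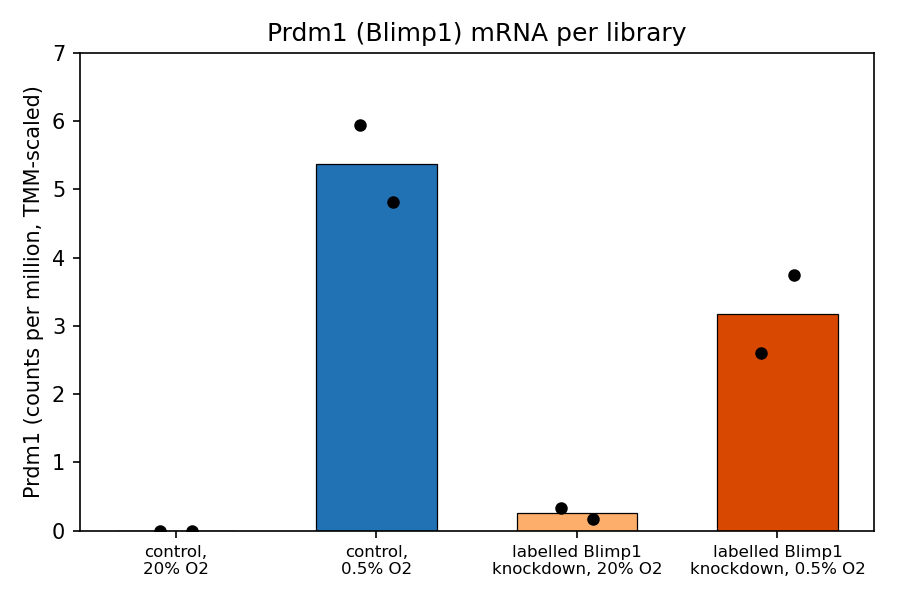
Prdm1 mRNA in each library in CPM (dots) with the group mean (bars), for control cells and cells labelled Blimp1 knockdown at 20% and 0.5% O2. The hypoxic libraries lie between 2.60 and 5.95 CPM, and the highest normoxic library is at 0.329 CPM.

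The comparison of oxygen levels in control cells asks what 24 hours of low oxygen does to these metastatic cells. Low oxygen raised HIF targets and endoplasmic reticulum chaperones and lowered cell cycle and ribosome biogenesis genes. Glycolysis and ATF4 genes rose as well, but their camera calls were lost with an estimated correlation (adjusted p = 0.141 and 0.10). The largest rises by fitted value were of Il11 (289 against 1 counts, ratio 268, 95% counting interval 47.8 to 10600), Pde2a (472 against 2 counts, ratio 219, interval 60.3 to 1810), Nat8l (log2 fold change 7.59, SE 0.18), Cldn4 (7.49, SE 0.21), Atp13a4 (38 against 0 counts, at least 11.8-fold), Adm (6.56, SE 0.19), Chrna1 (6.42, SE 0.17) and Csf2 (6.23, SE 0.17). For rises from few normoxic counts these SEs understate counting error. Nat8l had 7 such counts (ratio 199, 95% counting interval 96.2 to 495), Cldn4 5 (ratio 188, interval 80.2 to 580) and Adm 10 (ratio 96.3, interval 52.2 to 201). The place of Atp13a4 rests on its fitted value, since its bound leaves room for genes outside this ranking to have risen more. The largest falls were of Ranbp3l (-3.60, SE 0.11), Vsig1 (-2.98, SE 0.085), Cad (-2.83, SE 0.043), Rangrf (-2.82, SE 0.17), the pancreatic factor Pdx1 (-2.76, SE 0.086), Wnk4 (-2.73, SE 0.11), Apoc2 (-2.70, SE 0.14) and Dna2 (-2.70, SE 0.13). In all, 10144 of 13004 genes were called by edgeR, 5121 higher and 5023 lower in hypoxia, or 6010 higher and 4219 lower with upper-quartile factors. At least 2-fold changes were called for 3485 genes, 2310 higher and 1175 lower, or 2614 and 871 with upper-quartile factors.

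Of 34 tested HIF targets outside glycolysis, 32 rose and 0 fell in control cells (median log2 fold change 2.15, camera adjusted p = 3.4e-12). They include Ndrg1 (4.98, SE 0.040), Serpine1 (4.46, SE 0.035), Ero1l (3.82, SE 0.040) and Vegfa (3.54, SE 0.043). Of 22 glycolysis genes, 21 rose and 1 fell (median 1.17, camera adjusted p = 1.85e-07, and 0.141 with an estimated correlation). Pfkp rose by 3.64 (SE 0.054) and Slc2a1 by 2.64 (SE 0.034). All 38 G1/S and DNA replication genes fell (median -1.22, camera adjusted p = 3.4e-12), and so did all 33 G2/M and mitosis genes (median -1.27, camera adjusted p = 3.4e-12). Top2a fell by 1.65 (SE 0.033), Ccna2 by 1.94 (SE 0.039) and Tk1 by 2.27 (SE 0.055). The 25 ribosome biogenesis genes all fell (median -1.47, camera adjusted p = 2.86e-11), among them Nolc1 (-1.76, SE 0.035) and Ncl (-1.47, SE 0.030). Cytosolic ribosomal protein genes fell less, 70 of 78 with 2 higher (median -0.34, camera adjusted p = 1.12e-08, estimated correlation 0.368). Nuclear genes of the respiratory chain fell in 50 of 59 and rose in 1 (median -0.54, camera adjusted p = 3.69e-09, estimated correlation 0.229).

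Among stress genes, 17 of 20 ATF4 and amino acid response genes rose and 3 fell in control cells (median 1.01, camera adjusted p = 3.12e-05, estimated correlation 0.10). Atf3 rose by 5.30 (SE 0.079) and Ddit3 by 4.96 (SE 0.081). Of 18 endoplasmic reticulum chaperones 16 rose and 1 fell (median 0.64, camera adjusted p = 3.26e-05), including Hspa5 (2.30, SE 0.031). NF-kB and inflammatory cytokine genes rose in 14 of 20 and fell in 2 (median 1.06, camera adjusted p = 0.00102, estimated correlation 0.106), with Ptgs2 at 3.40 (SE 0.034) and Lif at 2.54 (SE 0.054). Kras and MAPK output genes rose in 13 of 19 and fell in 4 (median 0.55, camera adjusted p = 0.0105, estimated correlation 0.106). Mesenchymal genes rose in 13 of 20 and fell in 4 (median 0.50, camera adjusted p = 0.0297, estimated correlation 0.141), including Fn1 (2.41, SE 0.034). Cholesterol biosynthesis genes fell in 16 of 24 and rose in 4 (median -0.18, camera adjusted p = 0.0419, estimated correlation 0.186). Of 9 tested Blimp1 targets known from lymphocytes 7 rose and 2 fell (median 2.31, camera adjusted p = 0.0419, estimated correlation 0.198), a call lost without the second control normoxia library (camera adjusted p = 0.0538). They include Klf2 (4.23, SE 0.11) and Fos (4.06, SE 0.12).

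Several other lists did not pass the camera test in control cells. CDK inhibitors and p53 targets rose in 10 of 18 and fell in 6 (camera adjusted p = 0.0877), with Cdkn1a 4.74 higher (SE 0.063). Interferon and antigen presentation genes rose in 13 of 19 and fell in 3 (camera adjusted p = 0.073), a list that passed without the first (0.0287) or the second (0.0388) control normoxia library. Extracellular matrix genes rose in 16 of 28 and fell in 9 (camera adjusted p = 0.0779), with Mmp13 5.66 (SE 0.083) and P4ha2 3.77 (SE 0.058) higher. Epithelial genes rose in 11 of 21 and fell in 8 (camera adjusted p = 0.328), with Krt7 lower (-1.37, SE 0.031). Pancreatic and ductal lineage factors rose in 9 of 16 and fell in 6 (median 0.15, mean -0.18, camera adjusted p = 0.701), with Hnf4a lower (-1.61, SE 0.037). Structural and nuclear RNAs rose in 2 of 4 (camera adjusted p = 0.226), a list that passed without the first control normoxia library (0.0391), with Malat1 2.43 higher (SE 0.037). None of the 13 mitochondrially encoded genes was in the table.

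A few genes usually read as markers of other cell types rose from very low levels in hypoxia. All 3 tested endothelial markers rose in control cells (median 4.18, camera adjusted p = 0.0419, estimated correlation 0.198), Kdr from 2 to 53 counts. They also rose in knockdown-labelled cells (median 2.99, or 2.85 with Cdh5 at its bound, camera adjusted p = 0.0796, and 0.0377 without the filter on low counts). Vwf was no longer called there with DESeq2 (adjusted p = 0.0955). Immune cell markers rose in 4 of 5 tested genes and fell in 1 in control cells (camera adjusted p = 0.249), and in knockdown-labelled cells the numbers were the same (camera adjusted p = 0.404). Csf1r went from 3 to 58 counts in control cells and from 0 to 50 counts in knockdown-labelled cells. Cd14, the 1 marker that fell, was abundant in all groups, so the line itself expresses it. Both tested fibroblast markers of 11 listed rose in each line, Pdgfra and Col1a1. The single tested hepatocyte marker of 11, Ttr, had 1 to 37 counts per group. Of 14 acinar and endocrine markers only Cela1 was tested, and it fell in hypoxia in control cells (log2 fold change -0.93) and in knockdown-labelled cells (-1.56). Lyz2, Tyrobp and Cd52 had 1 count each over all 8 libraries.

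The comparison of oxygen levels in knockdown-labelled cells asks the same question where the label names Blimp1 as targeted. HIF targets again rose and ribosome biogenesis again fell, while mitotic genes moved little and cholesterol biosynthesis genes rose. The largest rises were of Atp13a4 (759 against 0 counts, at least 245-fold), Efr3b (755 against 3 counts, ratio 244, 95% counting interval 83.1 to 1180), Adm (ratio 73.3, interval 24.8 to 358), P2rx7 (log2 fold change 5.52, SE 0.18), Tmeff2 (4.99, SE 0.14), Chrna1 (4.65, SE 0.11), Atf3 (4.64, SE 0.092) and Zan (4.47, SE 0.15). The largest falls were of Fkbp11 (-2.85, SE 0.18), Clic6 (-2.79, SE 0.10), Cad (-2.71, SE 0.045), Gja1 (-2.68, SE 0.094), Fam195a (-2.66, SE 0.16), Scara3 (-2.65, SE 0.057), Prl2c2 (-2.60, SE 0.046) and Tsen2 (-2.48, SE 0.12). By edgeR 10106 genes were called, 5099 higher and 5007 lower (5591 and 4584 with upper-quartile factors), and 3085 of them changed at least 2-fold, 2093 higher and 992 lower (2263 and 808).

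Of 34 HIF targets, 32 rose and 1 fell in knockdown-labelled cells (median 1.68, camera adjusted p = 7.26e-11), with Bnip3 at 4.23 (SE 0.054), and of 22 glycolysis genes 20 rose and 1 fell (median 1.04, camera adjusted p = 5.03e-07, estimated correlation 0.215). Ribosome biogenesis genes all fell (median -1.27, camera adjusted p = 1.32e-10), and so did all 78 ribosomal protein genes (median -0.73, camera adjusted p = 1.57e-16, estimated correlation 0.342). Respiratory chain genes fell in 57 of 59 and rose in 1 (median -0.48, camera adjusted p = 3.6e-10, estimated correlation 0.314). G1/S genes fell in 32 of 38 and rose in 3 (median -0.61, camera adjusted p = 5.85e-07). G2/M genes fell in 20 of 33 and rose in 11 (median -0.26, camera adjusted p = 0.178, and 0.0111 without the filter on low counts). Aurka rose by 0.69 (SE 0.039), whereas Ccna2 fell by 0.78 (SE 0.034). Cholesterol biosynthesis genes rose in 21 of 24 and fell in 1 (median 0.95, camera adjusted p = 7.22e-07), including Sc4mol (1.82, SE 0.039), Hmgcs1 (1.34, SE 0.041) and Sqle (1.14, SE 0.037).

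NF-kB genes rose in 17 of 20 and fell in 2 in knockdown-labelled cells (median 0.91, camera adjusted p = 3.25e-04, estimated correlation 0.124), and ATF4 genes rose in 13 of 20 and fell in 3 (median 0.44, camera adjusted p = 0.00797, estimated correlation 0.234). Interferon genes rose in 12 of 19 and fell in 2 (median 0.72, camera adjusted p = 0.032, estimated correlation 0.208), with Ifit3 2.76 higher (SE 0.16). Endoplasmic reticulum chaperones rose in 8 of 18 and fell in 8 (median 0.03, camera adjusted p = 0.959). Hspa5 rose by 0.67 (SE 0.030) and Pdia4 fell by 1.22 (SE 0.046). Kras output genes rose in 6 of 19 and fell in 10 (camera adjusted p = 0.279, and 0.0392 without the filter). Mesenchymal genes rose in 6 of 20 and fell in 10 (median -0.23, mean 0.045, camera adjusted p = 0.768). Blimp1 targets rose in 4 of 9 and fell in 3 (camera adjusted p = 0.318). CDK inhibitors and p53 targets rose in 10 of 18 and fell in 6 (camera adjusted p = 0.318). Epithelial genes (10 of 21 higher, 5 lower), extracellular matrix genes (15 of 28 higher, 10 lower) and lineage factors (8 of 16 higher, 6 lower) did not pass camera either, with adjusted p of 0.518, 0.318 and 0.768. Structural RNAs rose in 2 of 4 and fell in 2 (median -0.04, which turned positive with upper-quartile factors, camera adjusted p = 0.768).

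Across the 13004 genes the log2 fold changes of the lines under low oxygen correlated with Pearson's r = 0.797 and Spearman's rho = 0.8003, and without the filter on low counts Pearson's r was 0.524. These comparisons share no library. Of the genes called in control cells 87.31% had the same sign in knockdown-labelled cells, and of those called with at least 2-fold changes 95.01%. Among the latter, the median ratio of the knockdown-labelled to the control response was 0.732. These genes were selected by their control response, which by itself can lower the ratio. Over all tested genes the median absolute log2 fold change was 0.573 in control and 0.54 in knockdown-labelled cells.

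**Figure D2:**
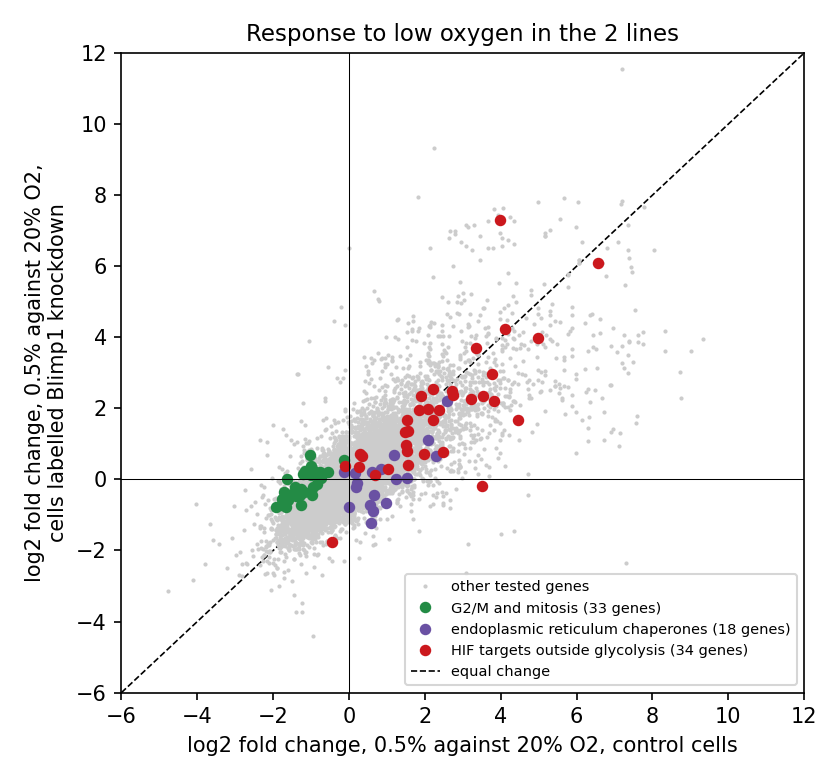
Log2 fold change at 0.5% against 20% O2 of each tested gene in control cells (x axis) and in cells labelled Blimp1 knockdown (y axis), with 3 gene lists in colour and a dashed line of equal change. G2/M and mitosis genes and endoplasmic reticulum chaperones lie off the line, with medians of -1.27 and 0.64 in control cells against -0.26 and 0.03 in the other line, and HIF targets have medians of 2.15 and 1.68. Values of genes without counts in a group are fitted and depend on the prior count.

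The comparison of the lines in normoxia asks what the knockdown label comes with where control cells have no Prdm1 counts. Cholesterol biosynthesis genes were lower in knockdown-labelled cells. NF-kB and inflammatory cytokine genes were higher, a camera call lost with an estimated correlation (adjusted p = 0.0949). The largest rises were of Prl2c3 (log2 fold change 5.70, SE 0.16), Il11 (46 against 1 counts), Prl2c2 (4.36, SE 0.059), Bcl2l15 (4.22, SE 0.25), Cxcl5 (4.09, SE 0.089), Nat8l (3.96, SE 0.38), Cxcl3 (3.86, SE 0.17) and Pde2a (26 against 2 counts). The largest falls were of Cldn3 (-3.13, SE 0.16), Bst1 (-2.94, SE 0.091), Aldoc (-2.85, SE 0.19), Smtnl2 (-2.84, SE 0.18), Sel1l3 (-2.51, SE 0.19), Ly6e (-2.41, SE 0.047), Slc4a11 (-2.33, SE 0.17) and Lpin1 (-2.31, SE 0.14). By edgeR 6159 genes were called, 3042 higher and 3117 lower (3346 and 2802 with upper-quartile factors), against 4025 in all with DESeq2 and 1840 with an assumed biological coefficient of variation of 0.1. By edgeR 831 changed at least 2-fold, 475 higher and 356 lower (314 and 292 with DESeq2).

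All 24 cholesterol biosynthesis genes were lower in normoxia (median -1.32, camera adjusted p = 1.35e-19), 20 of them at least 2-fold. Hmgcs1 fell from 317 ± 0.444 CPM in control to 102 ± 2.15 CPM in knockdown-labelled cells (SD, n = 2, log2 fold change -1.63, SE 0.040), and Cyp51 (-1.66, SE 0.046), Fdps (-1.54, SE 0.042) and Sqle (-1.28, SE 0.037) were lower as well. NF-kB and cytokine genes were higher in 15 of 20 and lower in 2, or 3 adjusted over the list alone (median 0.99, camera adjusted p = 1.12e-05, estimated correlation 0.0949), with Cxcl1 at 2.57 (SE 0.090) and Csf1 at 1.24 (SE 0.064). G2/M genes were slightly higher in 20 of 33, or 22 adjusted over the list alone, and none was lower (median 0.14, camera adjusted p = 5.44e-05, estimated correlation 0.0949). Ribosomal protein genes were higher in 46 of 78, or 51 adjusted over the list alone, and lower in 5 (median 0.12, camera adjusted p = 2.42e-05, estimated correlation 0.603). Lineage factors were higher in 8 of 16 and lower in 1 (median 0.13, camera adjusted p = 0.0105, estimated correlation 0.171), with Tff1 at 1.74 (SE 0.084). Glycolysis genes were lower in 11 of 22 and higher in 4 (median -0.13, camera adjusted p = 0.0326, estimated correlation 0.529), a call lost without the first knockdown-labelled normoxia library (0.0893).

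Other lists did not pass camera in normoxia. Epithelial genes were higher in 5 of 21 and lower in 8, or 9 adjusted over the list alone (camera adjusted p = 0.238), with Krt7 lower (-2.20, SE 0.033) and Muc1 higher (2.25, SE 0.063). Mesenchymal genes were higher in 10 of 20 and lower in 5 (camera adjusted p = 0.238), with Cdh2 2.09 higher (SE 0.11). HIF targets were higher in 9 of 34 and lower in 14, or 15 adjusted over the list alone (median -0.14, or -0.12 with empty groups at their bound, camera adjusted p = 0.15, and 0.0427 without the filter). Extracellular matrix genes were higher in 6 of 28 and lower in 15, or 16 adjusted over the list alone (median -0.17, mean 0.01, camera adjusted p = 0.0714, and 0.0192 without the filter). Ribosome biogenesis genes were higher in 5 of 25 and lower in 14 (median -0.10, camera adjusted p = 0.0504), and passed with RLE factors (0.0426), without the filter (0.00838) and without the second knockdown-labelled normoxia library (0.0374). The camera adjusted p was 0.15 or more for G1/S genes (14 higher and 3 lower of 38), Kras output (10 and 5 of 19), respiratory chain genes (12 and 11 of 59, median 0.01 and below 0 with RLE factors), CDK inhibitors and p53 targets (8 and 5 of 18, 9 higher adjusted over the list alone), ATF4 genes (7 and 4 of 20), chaperones (4 and 4 of 18), interferon genes (5 and 2 of 19), Blimp1 targets (3 and 2 of 9) and structural RNAs (2 and 0 of 4).

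The comparison of the lines in hypoxia asks how the lines differ when control cells carry Prdm1 mRNA. Knockdown-labelled cells had higher cell cycle gene expression and had lower levels of HIF targets, chaperones and Kras output genes than control cells. ATF4 genes were lower too, a camera call lost with an estimated correlation (adjusted p = 0.0552). The largest rises were of Cxcl5 (log2 fold change 4.48, SE 0.082), Atp13a4 (4.34, SE 0.16), Ccl2 (4.06, SE 0.17), Prl2c2 (3.46, SE 0.10), Muc1 (3.39, SE 0.077), Prl2c3 (3.22, SE 0.19), Efr3b (3.14, SE 0.13) and Aqp5 (2.87, SE 0.13). The largest falls were of Cldn4 (-3.95, SE 0.13), Cldn3 (-3.23, SE 0.18), Bst1 (-3.18, SE 0.098), S100a14 (-3.07, SE 0.15), Has2 (-2.96, SE 0.11), Lif (-2.87, SE 0.055), Ctgf (-2.86, SE 0.033) and Ptk7 (-2.68, SE 0.13). By edgeR 8759 genes were called, 4357 higher and 4402 lower (3964 and 4801 with upper-quartile factors), against 5470 in all with the assumed coefficient of variation. By edgeR 1701 changed at least 2-fold, 892 higher and 809 lower (830 and 885 with upper-quartile factors).

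All 33 G2/M genes were higher in knockdown-labelled hypoxic cells (median 1.24, camera adjusted p = 7.73e-17), 24 of them at least 2-fold. Kif11 stood at 59.0 ± 0.76 CPM in control and 256 ± 1.75 CPM in knockdown-labelled cells (SD, n = 2, log2 fold change 2.12, SE 0.045), and Aurka (1.97, SE 0.045) and Kif20a (1.93, SE 0.041) were higher too. Of 38 G1/S genes 36 were higher (median 0.54, camera adjusted p = 4.14e-11), among them Dhfr (1.57, SE 0.063) and Fen1 (1.36, SE 0.050). HIF targets were lower in 26 of 34 and higher in 6 (median -0.66, camera adjusted p = 1.34e-05), including Serpine1 (-1.99, SE 0.030), Ero1l (-1.67, SE 0.032) and Vegfa (-1.33, SE 0.034). Chaperones were lower in 17 of 18 and higher in 1 (median -0.65, camera adjusted p = 5.75e-07), with Hspa5 at -1.78 (SE 0.030). ATF4 genes were lower in 19 of 20 and higher in 1 (median -0.66, camera adjusted p = 5.75e-07, estimated correlation 0.0552). Kras output genes were lower in 16 of 19 and higher in 3 (median -0.83, camera adjusted p = 2.19e-05), including Ier3 (-1.90, SE 0.034) and Areg (-1.80, SE 0.043). Ribosomal protein genes were lower in 62 of 78, or 64 adjusted over the list alone, and higher in 7 (median -0.26, camera adjusted p = 5.75e-07, estimated correlation 0.492).

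Weaker list differences in hypoxia were of glycolysis (13 of 22 lower and 5 higher, median -0.22, camera adjusted p = 0.0358, estimated correlation 0.475), CDK inhibitors and p53 targets (12 of 18 lower and 3 higher, camera adjusted p = 0.0358, estimated correlation 0.328) and lineage factors (11 of 16 higher and 5 lower, camera adjusted p = 0.0358, estimated correlation 0.182). Hnf4a (1.34, SE 0.037) and Pdx1 (1.52, SE 0.10) were higher and Slc2a1 was lower (-1.38, SE 0.031). Epithelial genes (4 of 21 higher, 12 lower) and extracellular matrix genes (9 of 28 higher, 16 lower) each had a camera adjusted p of 0.0524. Without the filter these fell to 0.0197 and 0.0166, and both lists also passed without the first knockdown-labelled hypoxia library (0.0376 and 0.04). Extracellular matrix genes further passed without the second knockdown-labelled hypoxia library (0.0467) and without the first control hypoxia library (0.0282). Mesenchymal genes were higher in 6 of 20 and lower in 10 (camera adjusted p = 0.246), with Fn1 at -2.34 (SE 0.033). NF-kB genes were higher in 12 of 20 and lower in 7 (camera adjusted p = 0.106), with Csf1 higher (2.03, SE 0.057) and Ptgs2 lower (-1.92, SE 0.030). Cholesterol biosynthesis genes were higher in 5 of 24 and lower in 12 (median -0.10, camera adjusted p = 0.347). Ribosome biogenesis genes were higher in 13 of 25, or 14 adjusted over the list alone, and lower in 5 (camera adjusted p = 0.0778). Blimp1 targets were higher in 2 of 9 and lower in 6 (camera adjusted p = 0.125), with Fos lower (-1.98, SE 0.084) and Bcl6 higher (1.22, SE 0.065). Interferon genes (7 of 19 higher, 5 lower, median -0.19, mean 0.23), respiratory chain genes (24 of 59 higher, 15 lower, median 0.01 and below 0 with upper-quartile factors) and structural RNAs (0 of 4 higher, 3 lower) had camera adjusted p of 0.791, 0.377 and 0.151.

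The fold changes between the lines at the 2 oxygen levels, which share no library, correlated across genes with r = 0.459 and rho = 0.452, and without the filter on low counts r was 0.176. Of the genes called in normoxia 75.43% had the same sign in hypoxia, and of those with at least 2-fold changes 86.4%.

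**Figure D3:**
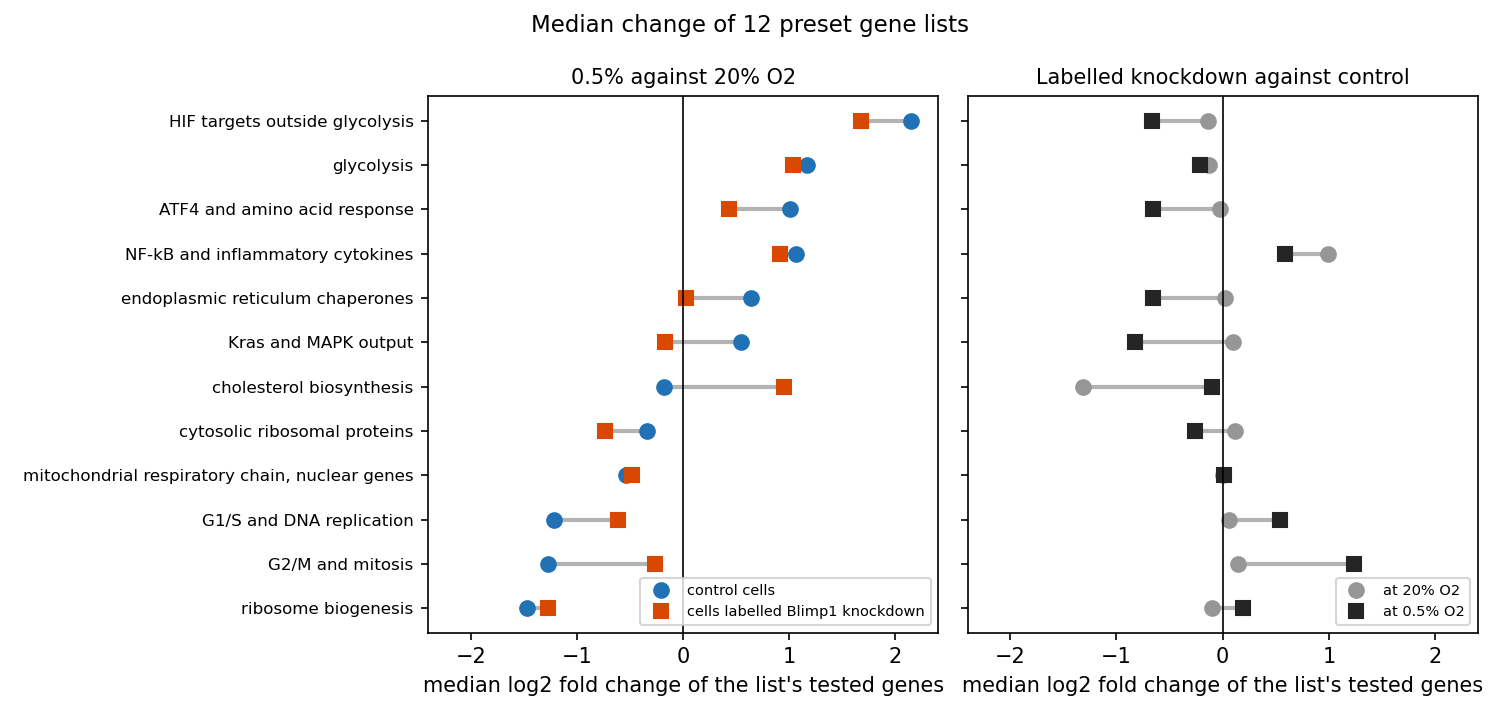
Median log2 fold change of 12 gene lists, for 0.5% against 20% O2 in each line (left) and for cells labelled Blimp1 knockdown against control at each oxygen level (right). The points lie far apart between the lines for G2/M and mitosis (-1.27 and -0.26) and cholesterol biosynthesis (-0.18 and 0.95), and close together for glycolysis (1.17 and 1.04). The respiratory chain medians between the lines lie near 0 and change sign with RLE factors in normoxia and with upper-quartile factors in hypoxia.

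Genes raised by hypoxia in control cells were often lower in knockdown-labelled hypoxic cells. Of the genes called in both comparisons, 2230 were higher in hypoxia and lower with the knockdown label, against 1734 for independent lists, and 2058 were lower in hypoxia and higher with the label, against 1683. With the assumed coefficient of variation, which calls fewer genes in each comparison, the first number was 1394. In the same direction, 1356 were higher in both (1716 for independent lists) and 1454 lower in both (1700). Among at least 2-fold changes these numbers were 432 (143.7), 168 (80.6), 239 (158.5) and 28 (73.1). Both comparisons use the control hypoxia libraries, which bends the values towards opposite signs. The observed covariance of log2 fold changes was -0.136 (r = -0.14), that in 20 simulations of unchanged groups -0.0132 (mean r = -0.49), and the difference -0.123. A split of the 2 control hypoxia libraries would leave 1 on each side and was not made, so part of the excess may come from sharing them.

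The interaction asks whether the response to low oxygen differs between the lines. By edgeR 6207 genes differed, 3085 with a higher and 3122 with a lower response in knockdown-labelled cells, or 2590 and 3724 with upper-quartile factors, and with the assumed coefficient of variation 1993 differed. For 1017 the difference was at least 2-fold, 432 higher and 585 lower, or 378 and 684 with upper-quartile factors. Mitotic and DNA replication genes fell less in knockdown-labelled cells, cholesterol genes had a higher response, and HIF targets, chaperones, ATF4 genes and Kras output genes rose less or fell. The largest positive terms were of Mep1a (3.05, SE 0.26), Maf (2.96, SE 0.22), Neurl1b (2.91, SE 0.16), Il1r1 (2.11, SE 0.071), Iqgap2 (2.03, SE 0.11) and Idi1 (2.0, SE 0.10). Neurl1b fell in control cells from 18.5 ± 1.18 to 5.85 ± 0.393 CPM and rose in knockdown-labelled cells from 14.4 ± 0.484 to 34.3 ± 0.208 CPM (SD, n = 2). The largest negative terms were of Nat8l (-5.79, SE 0.36), Cldn4 (-4.17, SE 0.97), Pde2a (-3.75, SE 0.72), Bcl2l15 (-3.61, SE 0.31), Il11 (-3.60, SE 0.84) and Csf2 (-3.12, SE 0.32). Those of Nat8l, Cldn4, Pde2a and Il11 rest on 1 to 7 counts in control normoxia, so their SEs may understate counting error.

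In the interaction, all 33 G2/M genes (median 1.03, camera adjusted p = 2.07e-19) and 34 of 38 G1/S genes, or 36 adjusted over the list alone (median 0.51, camera adjusted p = 1.03e-11), had a higher response in knockdown-labelled cells, and none a lower one. Cholesterol genes had a higher response in 23 of 24 (median 1.33, camera adjusted p = 7.72e-15). Ribosome biogenesis genes did so in 16 of 25, with 2 lower (median 0.28, camera adjusted p = 0.00112). A lower response was called for 16 of 18 chaperones with 1 higher (median -0.88, camera adjusted p = 2.54e-08), 18 of 20 ATF4 genes with 1 higher (median -0.63, camera adjusted p = 3.81e-08), 16 of 19 Kras output genes with 1 higher (median -0.75, camera adjusted p = 7.55e-08) and 18 of 34 HIF targets, or 20 adjusted over the list alone, with 6 higher (median -0.44, camera adjusted p = 6.4e-04). The response was also lower for 75 of 78 ribosomal protein genes with 1 higher (median -0.37, camera adjusted p = 4.02e-15, estimated correlation 0.349), 12 of 20 mesenchymal genes with 2 higher (median -0.57, camera adjusted p = 0.00293, estimated correlation 0.0608), 10 of 18 CDK inhibitors and p53 targets, or 11 adjusted over the list alone, with 2 higher (median -0.27, camera adjusted p = 0.00324, estimated correlation 0.193), and 5 of 9 Blimp1 targets with 1 higher (median -0.93, camera adjusted p = 0.01, estimated correlation 0.169).

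Single genes show the range of the interaction. Serpine1 rose by 4.46 in control and 1.67 in knockdown-labelled cells (interaction -2.79, SE 0.047). Hspa5 had an interaction of -1.63 (SE 0.043), Areg of -2.12 (SE 0.066), Hbegf of -1.74 (SE 0.050) and Cdkn1a of -1.93 (SE 0.11). Lif rose from 37.2 ± 0.474 to 216 ± 8.67 CPM in control cells and fell from 38.5 ± 2.03 to 29.6 ± 0.662 CPM in knockdown-labelled cells (SD, n = 2, interaction -2.92, SE 0.095). Kif11 (1.64, SE 0.060), Aurka (1.71, SE 0.064), Hmgcs1 (1.51, SE 0.054) and Cyp51 (1.74, SE 0.062) had positive terms. Glycolysis genes showed 3 higher and 8 lower responses of 22 (median -0.03, camera adjusted p = 0.413). The camera adjusted p was 0.234 or more for lineage factors (9 higher and 4 lower of 16), extracellular matrix genes (5 and 11 of 28), epithelial genes (5 and 9 of 21, 6 higher adjusted over the list alone), respiratory chain genes (18 and 10 of 59, median 0.05 and below 0 with upper-quartile factors), NF-kB genes (5 and 8 of 20, 7 higher adjusted over the list alone), interferon genes (3 and 4 of 19), endothelial markers (0 and 0 of 3) and immune markers (0 and 2 of 5). Structural RNAs showed 0 higher and 3 lower responses of 4 (median -1.15, camera adjusted p = 0.054), and passed with RLE factors (0.0499), without the filter (0.0266) and without the first (0.00214) or second (0.0198) control normoxia library.

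Upper-quartile factors moved the median log2 fold change of all genes in control cells under low oxygen from 0.029 to 0.162, and changes of that size are not told apart from scaling. The sign of a list median changed with RLE or upper-quartile factors only for the respiratory chain and structural RNA values named above.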

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

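The weighing tests in this part were chosen after the results they address were seen, except the test of library preparation for the cholesterol genes.

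Each result here was singled out because the response to low oxygen differed between the lines by a test of the difference itself. By edgeR 6207 genes had such an interaction. The lists with a called difference had median interactions (log2) of 1.33 for cholesterol biosynthesis, 1.03 for G2/M and mitosis, 0.51 for G1/S and DNA replication, 0.28 for ribosome biogenesis, -0.27 for CDK inhibitors and p53 targets, -0.37 for cytosolic ribosomal proteins, -0.44 for HIF targets outside glycolysis, -0.57 for mesenchymal genes, -0.63 for the ATF4 and amino acid response, -0.75 for Kras and MAPK output, -0.88 for endoplasmic reticulum chaperones and -0.93 for Blimp1 targets known from lymphocytes. With an estimated correlation the calls of CDK inhibitors and p53 targets (camera adjusted p = 0.193), ribosomal proteins (0.349), mesenchymal genes (0.0608) and Blimp1 targets (0.169) were lost. Single genes with a called interaction were Mep1a (3.05), Maf (2.96), Neurl1b (2.91), Il1r1 (2.11), Iqgap2 (2.03), Idi1 (2.0), Csf2 (-3.12), Il11 (-3.60), Bcl2l15 (-3.61), Pde2a (-3.75), Cldn4 (-4.17), Prdm1 (-5.39) and Nat8l (-5.79). The terms of Il11, Pde2a, Cldn4, Prdm1 and Nat8l rest on 0 to 7 counts in control normoxia.

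Mitotic genes fell in hypoxia in control cells (median -1.27) and much less in knockdown-labelled cells (median -0.26). The lowest median interaction under RLE or upper-quartile factors was 0.963. Such factors move all genes about alike, and the median interaction of all genes was -0.015 with TMM, -0.006 with RLE and -0.079 with upper-quartile factors. The list median could therefore hardly have changed, and the test does not decide how far scaling contributed. A common shift would leave the gap between these genes (1.03) and all genes (-0.015) in place. A response weaker by one factor for all genes would leave similar ratios for every list, but the ratio of knockdown-labelled to control medians was 0.205 for these genes, 0.886 for glycolysis and 0.864 for ribosome biogenesis. Mitotic genes were not alone in responding less. Control and knockdown-labelled medians were 0.64 and 0.03 for chaperones, 1.01 and 0.44 for ATF4 genes, and -1.22 and -0.61 for G1/S genes. Ribosomal protein genes went the other way, with medians of -0.34 and -0.73. Lower Prdm1 mRNA in hypoxia was a call lost with DESeq2 and without the first knockdown-labelled hypoxia library. It is the biological explanation that the design names, and the difference in mitotic genes may stem from it. It cannot be told apart from other differences between the derivatives, since the number of knockdown lines is 1.

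Cholesterol biosynthesis genes were lower in knockdown-labelled cells in normoxia (median -1.32). Differences between the preparations of a group's libraries were far smaller, with a largest group median of 0.057 over the 24 genes. These values compare only libraries within a group, so they cannot show a difference in preparation between the groups. Lower Prdm1 mRNA could not be tested as a source, because the highest Prdm1 count of a control normoxic library was 0, under the floor of 3. The state of the normoxic cultures, such as their density or medium, was not tested and stays open.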

How the results depend on the processing

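The assumed biological coefficient of variation was the one alternative added after the data were seen. Under RLE and upper-quartile factors every correlation and Prdm1 call kept its direction and its side of the threshold. Totals of called genes and the overlap stayed within 1.5 times their value, as did the totals in fits of only the 4 libraries of a comparison. Which of the higher and lower genes were more numerous turned in 6 alternatives and in 4 fits without 1 library. The 6 were the interaction with RLE factors (3157 higher and 3056 lower) and DESeq2 (2264 and 2080), the lines in normoxia with upper-quartile factors (3346 and 2802) and in the fit of 4 libraries (2900 and 2880), the lines in hypoxia with the assumed coefficient (2745 and 2725) and low oxygen in knockdown-labelled cells without the filter (5166 and 5224). Prdm1 in normoxia has no value in the fit of only the 4 normoxic libraries, where it was filtered out.

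The count for the lines in normoxia (6159) was 4025 with DESeq2. In the simulated counts DESeq2 also called fewer changed genes, 22% against 46% with edgeR at 1.2-fold and 74% against 86% at 1.5-fold. It gave no adjusted p for 253 genes in this comparison. Whether these account for the lower count was not tested. With the assumed coefficient the count in normoxia was 1840, that in hypoxia 5470 (8759), the interaction 1993 (6207), and the overlap of genes higher in hypoxia and lower with the label 1394 (2230). A larger assumed spread calls fewer small changes by construction, but this alternative also replaced the quasi-likelihood F test by a likelihood ratio test. The parts of the spread and of the test were not separated. Totals of at least 2-fold changes moved by less than 1.5 times under every alternative run. Of these, the genes higher in knockdown-labelled than control cells in normoxia were 314 with DESeq2 (475).

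Without the filter 20283 genes were tested, and the correlation of the hypoxia responses was 0.524 (0.797) and that between the lines' differences 0.176 (0.459). The latter was 0.486 with limma voom, and the cause was not tested. Leaving out 1 library gave 0.759 to 0.777 and 0.392 to 0.437, with more low-count genes tested (13324 to 13437) than in the full fit (13004).

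Prdm1 in normoxia ranged from 4.14 to 5.05 (fitted log2) when 1 library was left out, and its call was lost in 3 of 4 such fits. These fitted values depend on the prior count, because the control normoxia group was empty. Prdm1 in hypoxia ranged from -1.03 to -0.50, and the call was lost without the first knockdown-labelled hypoxia library. With DESeq2 it was -0.75 (adjusted p = 0.0997), and the cause was not tested.

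With an estimated inter-gene correlation 30 list results lost their camera call. The direction of fry, which does not compare a list with other genes, was opposite for lineage factors in control cells under low oxygen (adjusted p = 5.3e-04), mesenchymal genes in knockdown-labelled cells under low oxygen (0.0313) and endothelial markers between the lines in hypoxia (0.0454). These lists have medians and means of different sign or, for the endothelial markers, members that go both ways. Among results of named genes 37 calls were lost with the assumed coefficient. Calls of Rn45s, the ribosomal RNA precursor, were lost whenever 1 library of its comparison was left out.

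No pairing by replicate number was seen, since the correlations of the deviations of same-numbered libraries from their group means lay between -0.0132 and 0.0135. Counting error makes up much of these deviations, so a weak pairing could be missed. With the replicate block the counts were 10134, 10093, 6123, 8734 and 6205, in the order of the comparisons, and among list calls only ribosome biogenesis between the lines in normoxia changed (camera adjusted p = 0.0461).

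Depth limits Prdm1 in normoxia, where 0 counts in a control library taken alone allow up to 0.226 or 0.299 CPM.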

Other observations

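The tests on the number of genes with a count were chosen after it was seen, except the test of receptor genes, and no test was run on the other values in this part beyond the edgeR calls. Chemokine, cytokine and other inflammatory genes differed between the lines in opposite directions in hypoxia. Cxcl5 stood at 6.28 ± 0.872 CPM in control and 142 ± 8.84 CPM in knockdown-labelled cells (SD, n = 2), Ccl2 at 1.32 ± 0.0983 and 22.1 ± 0.461 CPM, and Csf1 at 34.8 ± 1.93 and 143 ± 0.646 CPM. Lif was lower, at 216 ± 8.67 and 29.6 ± 0.662 CPM, and so was Ptgs2, at 1800 ± 0.656 and 476 ± 6.9 CPM. Cxcl5 was already higher in normoxia, at 107 ± 0.879 CPM against 6.28 ± 0.29 CPM, whereas Lif was not called there (38.5 ± 2.03 against 37.2 ± 0.474 CPM).

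Genes of epithelial and pancreatic identity also went different ways. Krt7 was lower in knockdown-labelled cells at both oxygen levels, with 253 ± 8.63 against 1170 ± 8.85 CPM in normoxia and 82.4 ± 4.28 against 451 ± 15.3 CPM in hypoxia. Muc1 was higher at both, with 127 ± 4.59 against 26.6 ± 1.05 CPM and 112 ± 5.99 against 10.7 ± 1.1 CPM. Tff1 was higher as well, with 51 ± 3.04 against 15.1 ± 0.862 CPM and 117 ± 4.55 against 17.7 ± 0.316 CPM. Hmga2 had group means of 412 to 422 CPM in the other groups and 185 ± 0.697 CPM in knockdown-labelled hypoxic cells.

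Hypoxic libraries had more genes with at least 1 count (17018 to 17514) than normoxic ones (14603 to 15341). Library depth is argued against, since after thinning to the smallest library's total the lowest hypoxic library still had 1874 more such genes than the highest normoxic one. Cells of another type would bring their abundant transcripts, but over 13 abundant markers of immune cells, fibroblasts and endothelial cells the highest median of a type in a hypoxic group was 0.0764 CPM, while Csf1r and Kdr had at least 2.04 CPM. Single markers stood higher, Cd68 at 9.64 and 4.77 CPM and Col1a1 at 1.96 and 2.08 CPM in control and knockdown-labelled hypoxic cells, without Lyz2 (0 and 0.0433 CPM) or Col1a2 (0 and 0.0433 CPM) beside them. Genomic DNA or other reads spread over the genome cannot be told apart from low transcription in hypoxia. Reads without a feature, which such reads would raise, were 7.029% to 8.168% of a hypoxic library and 4.695% to 5.497% of a normoxic one, but unannotated or unspliced RNA would raise them too. The summed CPM of 1403 olfactory and vomeronasal receptor genes rose 1.57-fold in control cells (95% interval 1.33 to 1.84) and 1.41-fold in knockdown-labelled cells (1.22 to 1.63), on both sides of the 1.5-fold bound set for that test. The receptor genes with at least 1 count in a group rose more. They numbered 22 in normoxia and 79 in hypoxia in control cells, and 24 and 74 in knockdown-labelled cells. No bound was set for these numbers.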
